A study of Arabidopsis thaliana with 42 samples.

How the data were processed

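Total RNA of shoot and stem samples of Arabidopsis thaliana was labelled with biotin and hybridised to single-colour Affymetrix arrays, 42 in all, with 14 groups of 3. Per the labels the values are MAS5 signals, and the deposited unit is a linear signal intensity per probe set. The version of MAS5 and the settings behind it are not given in the sources used here. On every array the mean signal after trimming 2% at each end was 100, which points to the scaling of MAS5. No further normalization was applied before the fits. Signals of 0 did not occur, and no 2 arrays were identical. The number of arrays per group, not a read depth, limits the precision.

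Signals were used as log2(signal + 8.01), the offset being the median over arrays of the 25th percentile of signal. The 64 AFFX control probe sets were left out of the tests. Probe sets were kept where at least 3 arrays of a fit lay above the 40th percentile of their own array. The 21 arrays of the Col-0 organs were fitted together (16039 probe sets, 14 residual degrees of freedom), and the 24 arrays of inflorescence apices together (14630 probe sets, 16 degrees of freedom). Group means were fitted with limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with trend), and 16 contrasts between groups and 2 F tests were computed. All tests were two-sided. P-values were adjusted by Benjamini-Hochberg over the probe sets of each contrast. A probe set was called at an adjusted p under 0.05, and calls of at least 2-fold were counted as well. The letters A, B and C of replicates did not pair the samples of different groups, so no pairing was used. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

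The groups, the contrasts, the offset, the filter, 26 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The annotation gave a single gene for 13513 probe sets, several genes for 503 and none for 8730. It gave a symbol other than the locus name for 1580. Of 393 list entries 68 had a probe set under their gene name, so 8 of the 26 lists had the minimum of 3 measured members: floral promoters, carpel and ovule, anther and tapetum, organ primordium and polarity, cell cycle and photosynthesis, and, in the organs only, secondary wall polysaccharide and auxin response. To cover more of the annotated genes, 5 lists (histones, tapetum and pollen wall, Calvin cycle and photorespiration, thylakoid and light reactions, secondary wall xylan) and 22 families sharing a symbol, with at least 5 members, were added from the annotation before gene values were tested. The lists overlap, so the results of overlapping lists are not separate evidence. Among others, LHCB4.2 and PSAN are in the photosynthesis and thylakoid lists, and PRK, RCA and SBPASE in the photosynthesis and Calvin cycle lists. IRX15 is in both wall lists, and AT5G07230 and AMS are in both anther lists. Each gene was represented by its probe set of highest mean signal.

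Lists were tested with camera of limma, two-sided, with a preset correlation of 0.01 and again with an estimated correlation, adjusted by Benjamini-Hochberg over 231 tests in the organs and 270 in the genotypes. Named genes came from a fixed rule with 3 parts: a set of focal regulators, of which only UFO had a tested probe set; up to 4 called members with the largest change from each list whose test passed or that had at least 3 called members; and the 5 highest and 5 lowest changes among called genes with a symbol whose 2 groups did not overlap, which chance alone gives for 10% of genes with 3 arrays against 3. A first listing by this rule was too long, so the part for families was narrowed to families whose test passed, after part of that listing had been seen. Of the 7 mutated genes the annotation named a probe set only for CLV3 and UFO; LFY, AP1, AP2, AP3 and AG were therefore not analysed here. The 1 probe set of CLV3 lay below the filter on all 24 arrays. Gene names, chromosomes and gene order come from the TAIR10.1 annotation, and no coordinates are given because the genome build behind the array is not given in the sources used here.

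The bacterial poly-A control transcripts and the 3'/5' signal ratios of actin, GAPDH and ubiquitin controls were read from the AFFX probe sets. Sample titles of the node and of the Col-0 inflorescence apex carry a 2 after the replicate letter; this was seen in the labels before the control signals were. Alternatives to the main choices were quantile normalization, per-array median scaling, the offset divided by 4 and multiplied by 4, no filter and a 60th percentile filter, eBayes without trend and with robust variance, only the 2 groups compared or all 42 arrays in a fit, a replicate block, only probe sets with 1 gene and no shared-target suffix, the RNA 3'/5' ratio as a covariate and each array left out in turn. The counts of the mutant contrasts were also fixed to be taken against the mean of the other 6 mutants. Chosen after seeing the data were this same reference for the lists and named genes, the mean of the 7 mutants in place of the Col-0 inflorescence apex in the organ contrasts, and organ contrasts fitted without the node and Col-0 inflorescence apex arrays.

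The limma fit was tested on simulated data with 200 changed probe sets: it called 76.1% to 92.5% of changes of 1.5-fold, 95.5% to 100% of changes of 2-fold and 100% of changes of 4-fold, with at most 19 false calls. For each contrast the calls were counted again for the 10 splits of its 6 arrays into 3 and 3, and each F test for 100 labellings of the arrays.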

Results

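Transcript levels were measured in 42 samples of Arabidopsis thaliana shoots and stems on Affymetrix arrays of 22810 probe sets. The samples formed 14 groups of 3 arrays each. In 7 groups the strain was Col-0 and the organ differed: hypocotyl, vegetative apex, vegetative apex with young leaves, transition apex before bolting, inflorescence apex after bolting, second internode of the stem and first node. The other 7 groups were inflorescence apices of the mutants clv3-7, lfy-12, ap1-15, ap2-6, ap3-6, ag-12 and ufo-1, listed with Col-0 as their background. All plants grew on soil in continuous light. Median array signals lay between 36.3 and 45.7, and arrays of the same group correlated at 0.986 to 0.994 across probe sets, which are not independent replicates.

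Changes are log2 fold changes of the first-named group minus the second, with ± the standard error of the limma fit, and signals are means ± SD (n = 3). The labels do not say whether the 3 samples of a group came from separate plants, so the p-values measure only the spread between these samples, which may be technical. The 3 arrays per group limit the precision. Where the lower of 2 signals was under the offset of 8.01 added before taking logs, it is near the background, and the offset sets the size of the log2 change and its standard error, so that size is not exact; this holds for UFO in the vegetative apex, for IRX15 in the inflorescence apex and for AT1G22480 in the hypocotyl, among others. Expression differed among the 7 Col-0 organs for 15790 of 16039 probe sets (98.4%) and among the 8 inflorescence apex genotypes for 10253 of 14630 (70.1%).

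The transition apex was set against the vegetative apex to find transcripts that differ at the floral transition. AGL42, a MADS-box gene, rose in the transition apex by 2.91 ± 0.12, from a signal of 7.2 ± 1.0 to 106.7 ± 6.3, and UFO, an F-box gene of floral meristems, rose by 1.69 ± 0.13, from 1.73 ± 0.84 to 23.5 ± 2.2. THI2.1, which encodes an antimicrobial thionin, rose by 5.49 ± 0.12 to 863.9 ± 27.1, and WSD1, a wax ester synthase, rose by 3.96 ± 0.12. BCAT4, an enzyme of methionine chain elongation in glucosinolate synthesis, fell by 5.73 ± 0.08, from 1535.8 ± 26.5 to 21.2 ± 3.2. PYK10, a beta-glucosidase of endoplasmic reticulum bodies, fell by 4.29 ± 0.10, and DFR, an enzyme of anthocyanin synthesis, fell by 3.39 ± 0.11. The stress-response transcription factor genes STZ and ORA47 changed by -3.81 ± 0.10 and -3.41 ± 0.12.

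All 3 measured floral promoter genes (AGL42, FD and AGL24) rose in the transition apex, also when adjusted over the list alone. FD, the bZIP partner of the florigen FT, rose by 1.54 ± 0.12 and AGL24 by 0.40 ± 0.08. The list's adjusted p was 0.0077, with adjusted p = 0.18 with an estimated correlation. Of 10 photosynthesis genes 9 fell and 1 rose, with the same counts adjusted over the list alone (median -0.64, adjusted p = 8.9e-06, and adjusted p = 0.18 with an estimated correlation). LHCB4.2, a light-harvesting protein of photosystem II, fell by 0.76 ± 0.04 and the Calvin cycle kinase PRK by 0.80 ± 0.05, while LHCB4.3 rose by 1.12 ± 0.08. All 7 Calvin cycle and photorespiration genes fell (median -0.58, adjusted p = 8.9e-06, and adjusted p = 0.12 with an estimated correlation). Of 11 thylakoid genes 10 fell and 1 rose (median -0.59, adjusted p = 1.3e-05, and adjusted p = 0.18 with an estimated correlation). Of 69 plastid-encoded genes 59 fell, psbD by 1.08 ± 0.14, while 0 rose and 10 did not pass (median -0.49, adjusted p = 9.8e-16, and adjusted p = 0.18 with an estimated correlation). Of 6 histone genes 5 rose, HTB2 by 0.79 ± 0.07 (median 0.34, adjusted p = 0.034, and adjusted p = 0.35 with an estimated correlation).

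Of 9 genes linked to secondary wall xylan, 7 fell and 1 rose in the transition apex (median -0.64, adjusted p = 0.023, and adjusted p = 0.26 with an estimated correlation). TBL34, a xylan acetyltransferase gene, fell by 1.06 ± 0.12, and AT1G22480 rose by 1.48 ± 0.19. This list did not pass after quantile normalization (adjusted p = 0.071) or with 4 times the offset (adjusted p = 0.051), within 0.015 to 0.26 over its alternatives. The lists for carpel and ovule, anther and tapetum, organ primordium and polarity, cell cycle, secondary wall polysaccharide and auxin response did not pass (adjusted p = 0.21 to 0.87). In all, 8602 probe sets changed, 4905 higher and 3697 lower, of which 387 were at least 2-fold higher and 709 at least 2-fold lower. The log2 3'/5' ratio of the RNA controls differed too, 1.35 ± 0.18 in the vegetative apex and 1.68 ± 0.10 in the transition apex (SD, n = 3); with it as a covariate 6885 probe sets changed, 6514 of them shared, and the lists were not tested with it.

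The inflorescence apex, whose sample holds young flowers, was set against the transition apex, covering the time around bolting. The floral promoter AGL24 fell by 1.96 ± 0.08, from 156.5 ± 5.5 to 34.2 ± 3.1, and FD fell by 1.32 ± 0.12. UFO differed by 0.18 ± 0.13 and did not pass (adjusted p = 0.31). The thionin gene THI2.2 rose by 1.92 ± 0.12, RXF26 by 1.91 ± 0.23 and the defensin-like gene PDF2.1 by 1.79 ± 0.21. The plastid chaperonin gene Cpn60beta3 fell by 1.60 ± 0.06, GIS, a zinc finger regulator of trichomes, by 1.51 ± 0.15 and the cation exchanger gene CHX16 by 1.49 ± 0.21.

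Of the 3 floral promoters 2 fell, also when adjusted over the list alone (median -1.32, adjusted p = 0.0012, and adjusted p = 0.12 with an estimated correlation). Among 69 plastid-encoded genes 48 rose and 1 fell, with ndhG at 1.84 ± 0.15 (median 0.48, adjusted p = 9.2e-19, and adjusted p = 0.18 with an estimated correlation). Of 9 SWEET sugar transporter genes 4 rose and 1 fell; SWEET10 rose by 1.43 ± 0.16 and SWEET8 by 1.18 ± 0.14 (adjusted p = 0.028, and adjusted p = 0.19 with an estimated correlation). Of 11 thylakoid genes 6 fell, among them LHCB4.2 by 0.67 ± 0.04, and 1 rose (median -0.20, adjusted p = 0.046, and adjusted p = 0.47 with an estimated correlation). The photosynthesis list did not pass (adjusted p = 0.087), and the lists for carpel and ovule, anther and tapetum, organ primordium and polarity, cell cycle, secondary wall polysaccharide and auxin response did not either (adjusted p = 0.10 to 0.96). The Calvin cycle list had a median of -0.03 and a mean of 0.02. In all, 5155 probe sets changed, 2511 higher and 2644 lower, of which 213 were at least 2-fold higher and 126 at least 2-fold lower.

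The Col-0 inflorescence apex arrays stood apart in controls that are not plant genes. Added bacterial poly-A transcripts were higher on these 3 arrays and on the 3 node arrays than on the other 36: dap averaged 7.71 (log2 signal plus offset) in the inflorescence apex and 8.07 in the node against 3.20 on the other 36 arrays, and thr 6.70 and 7.15 against 3.52. The inflorescence apex was therefore also represented by the mean of the 7 mutants, an alternative chosen after seeing the data. Against the transition apex this gave 6369 probe sets, 3630 of them among the 5155. The floral promoters then had a median of -0.75 and did not pass (adjusted p = 0.089, within 4.9e-04 to 0.12 over the alternatives), and the thylakoid genes turned to a median of 0.09 (adjusted p = 0.57, within 0.041 to 0.57). The plastid-encoded genes passed with a median of 0.48, 47 higher and 2 lower, and the Calvin cycle list passed upward, with 5 of 7 genes higher (median 0.18, adjusted p = 0.029, within 0.029 to 0.96 over the alternatives).

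**Figure D1:**
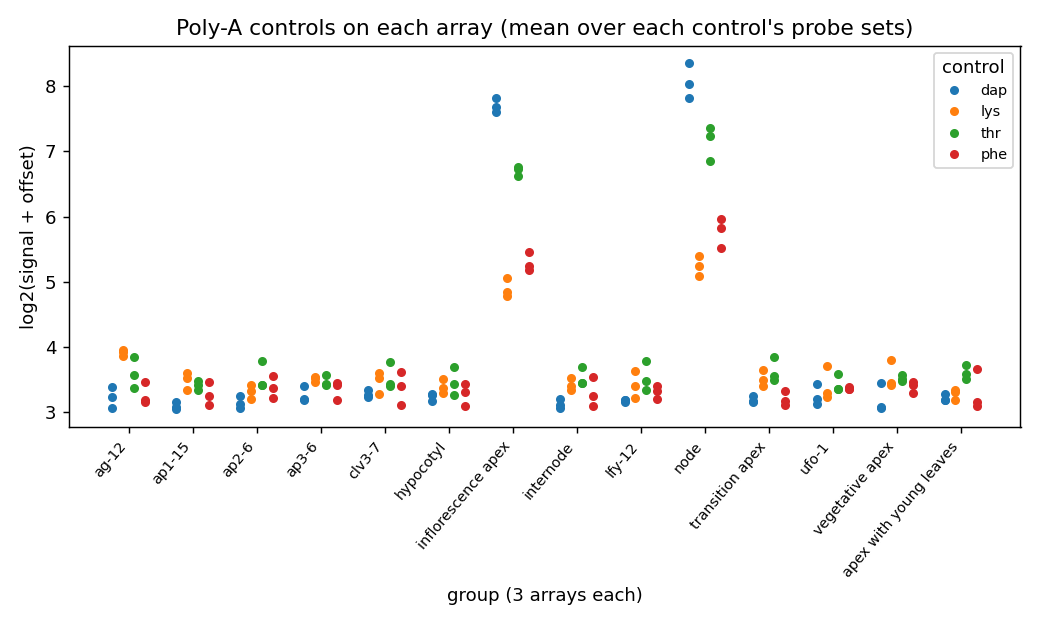
Signals of 4 added poly-A control transcripts (dap, lys, thr and phe) on each of the 42 arrays, as log2(signal + offset). For dap the lowest of the 6 inflorescence apex and node arrays was at 7.61 and the highest of the other 36 at 3.45.

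The inflorescence apex was also set against the vegetative apex, across the whole step from vegetative growth to flowering. THI2.1 rose by 5.53 ± 0.12, RXF26 by 4.62 ± 0.23 and WSD1 by 4.29 ± 0.12. REM22, a transcription factor gene of the B3 type, rose by 3.71 ± 0.22, from 12.1 ± 2.2 to 254.1 ± 21.5, and UFO rose by 1.88 ± 0.13. BCAT4 fell by 6.36 ± 0.08, PYK10 by 5.74 ± 0.10, DFR by 4.12 ± 0.11 and the jacalin-related lectin gene JAL34 by 3.66 ± 0.10. SPT, a bHLH gene of carpel development, rose by 1.17 ± 0.10 and PHV, a homeodomain gene of the upper organ side, by 0.76 ± 0.08.

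Photosynthesis genes fell, 9 of 10 with 1 higher (median -0.85, adjusted p = 1.2e-05, and adjusted p = 0.18 with an estimated correlation); LHCB4.2 fell by 1.42 ± 0.04 while LHCB4.3 rose by 1.61 ± 0.08. The counts adjusted over the list alone were again 9 lower and 1 higher. All 7 Calvin cycle and photorespiration genes fell (median -0.62, adjusted p = 9.0e-05, and adjusted p = 0.18 with an estimated correlation). Of 11 thylakoid genes 9 fell and 1 rose (median -0.80, adjusted p = 1.8e-05, and adjusted p = 0.18 with an estimated correlation). Of 6 histone genes 4 rose, HTB2 by 1.07 ± 0.07 (median 0.55, adjusted p = 0.029, and adjusted p = 0.33 with an estimated correlation). None of the other fixed lists passed (adjusted p = 0.18 to 0.96). In all, 9727 probe sets changed, 5464 higher and 4263 lower, with 637 at least 2-fold higher and 923 at least 2-fold lower; with the mean of the 7 mutants the count was 10781, of which 8522 were shared. Per-array median scaling left 48.1% of the changed probe sets higher, against 56.2%. With the RNA 3'/5' ratio as a covariate (1.83 ± 0.07 in the inflorescence apex) 6845 changed, 6538 of them shared. The mean of the 7 mutants moves with their own changes here too. With it the Calvin cycle median was -0.32 and the thylakoid median -0.46, and both lists passed. The histone list then had a median of 0.38 and did not pass (adjusted p = 0.15, within 0.0089 to 0.33 over the alternatives), and the dap control was again 7.71 in these inflorescence arrays against 3.20 on average elsewhere.

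The vegetative apex with young leaves was set against the vegetative apex, which separates young leaves from the apex. LrgB, a plastid glycolate and glycerate transporter, rose with young leaves by 1.91 ± 0.07, from 143.9 ± 11.4 to 563.5 ± 11.1, and NdhL, a subunit of the chloroplast NDH complex, by 1.95 ± 0.08. The methionine sulfoxide reductase gene MSRB6 rose by 2.50 ± 0.13 and the calmodulin-like gene CML38 by 2.17 ± 0.16. PTL, a trihelix gene of floral organ boundaries, fell by 1.16 ± 0.13, the expansin gene EXPA15 by 1.13 ± 0.06 and the beta-glucosidase gene BGLU47 by 1.11 ± 0.10. The lateral organ genes NUB and PHV fell by 0.87 ± 0.15 and 0.62 ± 0.08.

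All 10 photosynthesis genes rose with young leaves, also when adjusted over the list alone (median 0.91, adjusted p = 1.6e-13, and adjusted p = 0.10 with an estimated correlation). PRK rose by 1.28 ± 0.05 and SBPASE, another Calvin cycle enzyme, by 1.13 ± 0.07. All 7 Calvin cycle and photorespiration genes rose, among them the photorespiratory hydroxypyruvate reductase gene HPR by 1.39 ± 0.05 (median 0.91, adjusted p = 4.2e-11), and this list also passed with an estimated correlation (adjusted p = 0.043). All 11 thylakoid genes rose (median 0.70, adjusted p = 2.9e-14, and adjusted p = 0.10 with an estimated correlation). Of 69 plastid-encoded genes 58 rose and 1 fell (median 0.46, adjusted p = 2.1e-16, and adjusted p = 0.18 with an estimated correlation). No other fixed list passed (adjusted p = 0.15 to 0.99), and the carpel and ovule list had a median of 0.03 and a mean of -0.07. In all, 7737 probe sets changed, 3013 higher (38.9%) and 4724 lower, with 362 at least 2-fold higher and 121 at least 2-fold lower. With per-array median scaling 52.2% of the changed probe sets were higher.

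The second internode was set against the first node, a stem segment against the point of organ attachment. The node sample also holds side shoot and leaf base, which cannot be told apart from the node itself. In the internode HIS1-3, a linker histone gene, was higher by 2.80 ± 0.20, the sulfurtransferase gene STR18 by 2.60 ± 0.10 and CYP71B23 by 2.41 ± 0.12. IRX15, needed for xylan in secondary walls, was higher by 1.18 ± 0.21, at 932.8 ± 10.9 against 409.0 ± 22.3. In the node the metallothionein gene MT1C was at 758.6 ± 66.0 against 77.0 ± 4.3, so that internode minus node was -3.17 ± 0.11. PTL, the cold-regulated gene COR15A, SWEET14 and the cellulase-family gene GH9B8 also had lower levels in the internode, at -3.09 ± 0.13, -3.09 ± 0.14, -2.67 ± 0.18 and -2.44 ± 0.12.

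Of 9 xylan genes 8 were higher in the internode and 0 lower (median 1.01, adjusted p = 0.0013, and adjusted p = 0.18 with an estimated correlation). The xylan genes GUT2 and IRX15-L were higher by 0.91 ± 0.10 and 1.01 ± 0.15. The 3 secondary wall polysaccharide genes were all higher, also when adjusted over the list alone, but the list did not pass (adjusted p = 0.053); it passed with 4 times the offset (adjusted p = 0.0081, within 0.0081 to 0.26 over the alternatives). All 3 cell cycle genes were lower, with the same count adjusted over the list alone (median -0.53, adjusted p = 0.040, and adjusted p = 0.22 with an estimated correlation); PRL, an MCM7 subunit of the replicative helicase, fell by 1.03 ± 0.07. Of 15 serine carboxypeptidase-like genes 11 were lower and 2 higher, with SCPL45 at -1.47 ± 0.06 (adjusted p = 0.021, and adjusted p = 0.18 with an estimated correlation). Of 8 autophagy (ATG) genes 7 were higher, with ATG8E at 0.92 ± 0.11 (median 0.52, adjusted p = 0.0068, and adjusted p = 0.19 with an estimated correlation).

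Of 10 photosynthesis genes 8 were higher in the internode and 1 lower, and LHCB4.2 was higher by 0.75 ± 0.04 (median 0.41, adjusted p = 0.0059, and adjusted p = 0.33 with an estimated correlation). Of 11 thylakoid genes 10 were higher and 1 lower (median 0.41, adjusted p = 5.2e-04, and adjusted p = 0.26 with an estimated correlation). Among 69 plastid-encoded genes 40 were higher and 8 lower (median 0.27, adjusted p = 2.2e-04, and adjusted p = 0.50 with an estimated correlation). With quantile normalization the photosynthesis median was 0.07 (adjusted p = 0.46, within 0.0047 to 0.46 over the alternatives), the thylakoid list did not pass (adjusted p = 0.31, within 3.3e-04 to 0.31), and the plastid-encoded and cell cycle lists gave adjusted p = 0.073 (within 1.5e-04 to 0.50) and 0.053 (within 0.028 to 0.22). The poly-A control dap was 8.07 on the node arrays and 3.20 on average on the 36 arrays that include the internode. The remaining fixed lists did not pass (adjusted p = 0.17 to 0.91), and the organ primordium list had a median of 0.01 and a mean of -0.02. In all, 9180 probe sets differed, 4399 higher and 4781 lower, with 562 at least 2-fold higher and 716 at least 2-fold lower. With per-array median scaling 56.7% were higher.

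The hypocotyl was set against the internode, as stem-like organs at opposite ends of the shoot. The hypocotyl is of seedlings and the internode of bolted plants, so organ and plant stage cannot be told apart here. PYK10 was higher in the hypocotyl by 7.73 ± 0.10, at 2982.8 ± 228.5 against 6.2 ± 2.6, NAI2, needed for endoplasmic reticulum bodies, by 6.48 ± 0.07, and the lectin genes JAL33 and JAL22 by 7.02 ± 0.16 and 6.53 ± 0.12. AT1G22480, of the xylan list, was lower by 8.07 ± 0.19, against a hypocotyl signal of 3.9 ± 2.3, the pectin methylesterase gene PME61 by 5.71 ± 0.11, and IRX15 by 4.65 ± 0.21. The cellulase-family gene GH9B5 was at -4.43 ± 0.12. FDH, formate dehydrogenase, was lower by a log2 change of -3.39 ± 0.06. GH3.3, an auxin-conjugating enzyme, was higher by 2.39 ± 0.07.

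All 9 xylan genes were lower in the hypocotyl (median -3.52, adjusted p = 3.8e-06, and adjusted p = 0.12 with an estimated correlation). All 3 secondary wall polysaccharide genes were lower, also when adjusted over the list alone (median -3.52, adjusted p = 0.0072, and adjusted p = 0.18 with an estimated correlation). All 10 photosynthesis genes were lower, also when adjusted over the list alone, with LHCB4.2 at -1.81 ± 0.04 (median -1.252, adjusted p = 8.9e-07, and adjusted p = 0.18 with an estimated correlation). Of 7 Calvin cycle genes 6 were lower and 1 higher (median -1.15, adjusted p = 0.0023, and adjusted p = 0.18 with an estimated correlation), and all 11 thylakoid genes were lower (median -1.24, adjusted p = 1.5e-07, and adjusted p = 0.18 with an estimated correlation). Of 8 autophagy genes 7 were lower, ATG8H at -2.40 ± 0.19 (median -1.16, adjusted p = 0.0016, and adjusted p = 0.18 with an estimated correlation). All 3 cell cycle genes were higher, also when adjusted over the list alone, with the Aurora kinase gene AUR2 at 2.51 ± 0.08 (median 1.97, adjusted p = 0.014, and adjusted p = 0.18 with an estimated correlation). Of 69 plastid-encoded genes 39 were lower and 15 higher (median -0.34, adjusted p = 0.014, and adjusted p = 0.63 with an estimated correlation).

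The plastid-encoded list had a median of -0.13 after quantile normalization and did not pass (adjusted p = 0.58, within 0.013 to 0.63 over the alternatives). The other fixed lists did not pass (adjusted p = 0.15 to 0.87). In all, 12172 probe sets differed between hypocotyl and internode, 6652 higher (54.7%) and 5520 lower, with 2383 at least 2-fold higher and 1604 at least 2-fold lower. Per-array median scaling shifted the median of all probe sets by -0.25 and left 38.5% of the differing probe sets higher, and quantile normalization shifted it by -0.12 and left 48.1% higher.

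The internode was set against the inflorescence apex, a stem segment against the growing tip above it. IRX15 was higher in the internode by 6.45 ± 0.21, at 932.8 ± 10.9 against 3.2 ± 4.1, PME61 by 6.41 ± 0.11, IRX15-L by 5.86 ± 0.15 and the pectin methylesterase gene PMEPCRF by 5.49 ± 0.09. Among the lowest changes the subtilase gene SBT1.3 was at -5.95 ± 0.07, THI2.1 at -5.88 ± 0.12, the defensin-like gene LCR69 at -5.38 ± 0.06 and the histone gene HTB2 at -4.72 ± 0.07. EMS1, a receptor kinase gene of anther development, fell by 4.07 ± 0.10, PRL by 4.07 ± 0.07, GH3.3 by 3.86 ± 0.07 and YAB3, a gene of the lower organ side, by 3.73 ± 0.12.

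All 9 xylan genes were higher in the internode (median 5.68, adjusted p = 5.3e-06, and adjusted p = 0.12 with an estimated correlation). All 3 secondary wall polysaccharide genes were higher, also when adjusted over the list alone (median 5.86, adjusted p = 0.014, and adjusted p = 0.18 with an estimated correlation). All 10 photosynthesis genes were higher, also when adjusted over the list alone, with LHCB4.2 at 3.02 ± 0.04 (median 1.89, adjusted p = 8.8e-06, and adjusted p = 0.18 with an estimated correlation). All 7 Calvin cycle genes (median 1.14, adjusted p = 0.0014, and adjusted p = 0.18 with an estimated correlation) and all 11 thylakoid genes (median 1.68, adjusted p = 4.1e-06, and adjusted p = 0.18 with an estimated correlation) were higher. All 8 autophagy genes were higher, ATG8H by 3.75 ± 0.19 (median 0.87, adjusted p = 0.0051, and adjusted p = 0.18 with an estimated correlation). Among 69 plastid-encoded genes 44 were higher and 14 lower (median 0.74, adjusted p = 5.4e-04, and adjusted p = 0.52 with an estimated correlation). All 3 cell cycle genes were lower, also when adjusted over the list alone (median -3.29, adjusted p = 0.028, and adjusted p = 0.19 with an estimated correlation), as were all 6 histone genes (median -2.33, adjusted p = 0.012, and adjusted p = 0.29 with an estimated correlation).

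None of the other fixed lists passed in the internode against the inflorescence apex (adjusted p = 0.13 to 0.93), and the floral promoters had a median of -0.29 and a mean of 0.06. In all, 13597 probe sets differed, 6076 higher (44.7%) and 7521 lower, with 3097 at least 2-fold higher and 3662 at least 2-fold lower. Per-array median scaling shifted the median of all probe sets by 0.22 and left 53.7% higher. With the mean of the 7 mutants in place of Col-0, 14154 probe sets differed, 13016 of them shared, and the dap control differed here too, 7.71 in the inflorescence apex against 3.20 on average elsewhere.

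**Figure D2:**
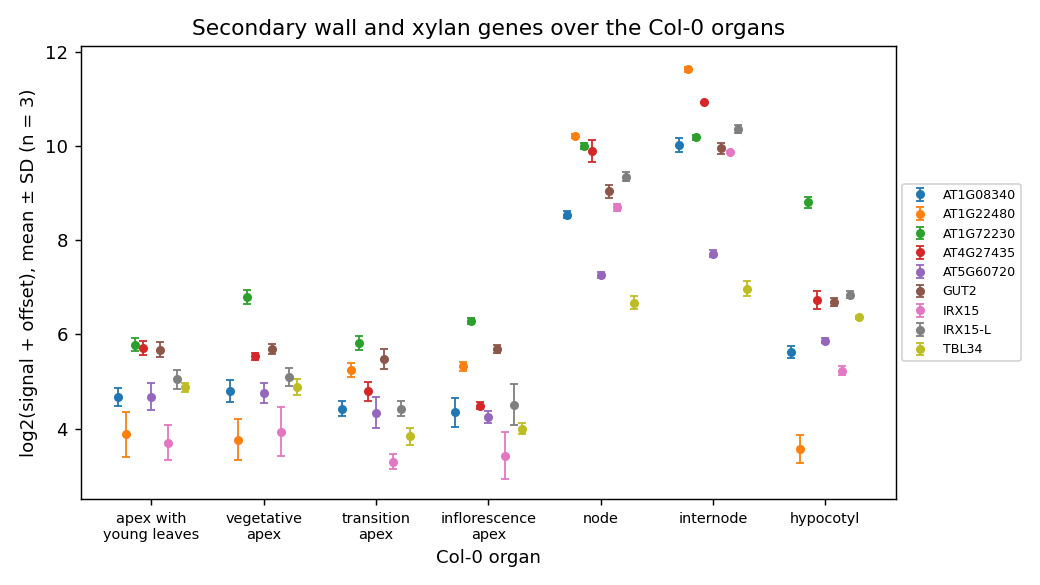
Levels of 9 genes linked to secondary wall xylan in the 7 Col-0 organs, as log2(signal + offset), mean ± SD of 3 arrays. All 9 were higher in the internode than in the inflorescence apex (median log2 difference 5.68) and than in the hypocotyl.

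Each mutant's inflorescence apex was compared with that of Col-0, which asks what loss of each floral or meristem regulator changes at the apex. Many transcripts moved the same way in all 7 mutants: 77 probe sets were higher and 58 lower in every one. The photosynthetic plastid-encoded genes ndhF, petN, petD and ndhG were lower in all 7, by a mean log2 change of -2.25, -1.53, -1.40 and -1.14, as were rps14 at -1.54, QQS, an orphan gene linked to starch, at -2.24 and GILT at -1.61. ECS1 and the peroxidase gene PRXR1 were higher in all 7, by 0.67 and 0.66. Of the 58 lower probe sets 8 were plastid-encoded. All 7 contrasts use the same 3 Col-0 arrays, on which the dap control was at 7.71, against 3.20 on average over the 36 arrays that include the mutants. Each mutant was also set against the mean of the other 6 mutants. This reference was fixed in advance for the counts and chosen after seeing the data for lists and genes. It moves with the changes of those 6 mutants, so a difference from it need not be a change in the mutant named.

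The clv3-7 mutant carries a change in CLV3, which encodes the peptide that limits the size of the shoot meristem. CLV3 itself had a signal of 6.06 ± 5.68 in clv3-7 and 6.22 ± 7.27 in Col-0 and was below the filter, so it was not tested. Cpn60beta3 rose by 1.21 ± 0.09, FD by 0.96 ± 0.12, from 45.6 ± 4.9 to 96.2 ± 14, and the clock gene GI by 0.83 ± 0.11. The plastid-encoded genes petD and ndhG fell by 2.11 ± 0.17 and 1.95 ± 0.23. Of 6 glycosyl hydrolase 9 genes 2 rose, GH9C2 by 0.59 ± 0.07 and GH9B7 by 0.34 ± 0.06 (median 0.30, adjusted p = 0.025, and adjusted p = 0.095 with an estimated correlation). Of 69 plastid-encoded genes 25 fell and 0 rose (median -0.28, adjusted p = 2.4e-12, and adjusted p = 0.34 with an estimated correlation), and 40 were lower against the other 6 mutants (median -0.36, adjusted p = 1.1e-17). The photosynthesis list did not pass against Col-0 (adjusted p = 0.40) and was lower against the other 6 mutants, with 9 of 10 genes down (median -0.31, adjusted p = 1.4e-08, within 1.4e-08 to 0.61 over the alternatives); the thylakoid and Calvin cycle lists then passed too, with 8 of 11 and 4 of 7 genes lower (medians -0.28 and -0.16). No other fixed list passed (adjusted p = 0.064 to 0.79), and the carpel and ovule list had a median of 0.08 and a mean of -0.01. In all, 2793 probe sets changed, 1521 higher and 1272 lower, with 26 at least 2-fold higher and 63 at least 2-fold lower; against the other 6 mutants the count was 4779, of which 1733 were shared.

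The lfy-12 mutant lacks normal LFY, the transcription factor that specifies floral meristems. UF3GT rose in lfy-12 by 1.97 ± 0.13, from 23.7 ± 3.8 to 116.1 ± 12, DFR by 1.68 ± 0.14 and COR15A by 2.31 ± 0.16. Genes of sporogenous tissue and anthers fell: SPL, or SPOROCYTELESS, by 1.45 ± 0.20 and EMS1 by 0.63 ± 0.08. REM22 fell by 2.51 ± 0.11, from 254.1 ± 21.5 to 38.5 ± 8.5, SP1L2 by 2.17 ± 0.17 and the chromatin remodelling gene chr31 by 2.1 ± 0.12, while a further probe set of chr31 was at -0.68. UFO was level, at 27.8 ± 3.8 against 27.7 ± 1.4 (log2 change -0.00 ± 0.18, not passed).

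All 10 photosynthesis genes rose in lfy-12, also when adjusted over the list alone, with LHCB4.2 at 1.15 ± 0.06 and PRK at 0.93 ± 0.06 (median 0.63, adjusted p = 1.3e-16, and adjusted p = 2.4e-04 with an estimated correlation). Of 7 Calvin cycle genes 6 rose (median 0.57, adjusted p = 1.7e-09, and adjusted p = 8.3e-04 with an estimated correlation), and all 11 thylakoid genes rose (median 0.54, adjusted p = 1.3e-16, and adjusted p = 0.0017 with an estimated correlation). All 4 floral promoters rose, also when adjusted over the list alone, among them the MADS-box genes AGL71 by 1.12 ± 0.26 and AGL24 by 0.90 ± 0.13 (median 0.81, adjusted p = 9.3e-05, and adjusted p = 0.0062 with an estimated correlation). Of 6 anther and tapetum genes 4 fell, 5 when adjusted over the list alone (median -0.64, adjusted p = 0.0021, and adjusted p = 0.021 with an estimated correlation). Of 19 UDP-glycosyltransferase genes 7 rose and 1 fell (adjusted p = 0.045, and adjusted p = 0.23 with an estimated correlation), and of 69 plastid-encoded genes 16 rose and 11 fell (adjusted p = 0.022, and adjusted p = 0.75 with an estimated correlation).

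The plastid-encoded list in lfy-12 did not pass after quantile normalization (adjusted p = 0.27, within 1.4e-06 to 0.75 over the alternatives), nor the UDP-glycosyltransferases with per-array median scaling (adjusted p = 0.061, within 0.0046 to 0.23). The other fixed lists did not pass (adjusted p = 0.22 to 0.78), and the organ primordium list had a median of 0.02 and a mean of -0.16. In all, 3952 probe sets changed, 1950 higher and 2002 lower, with 111 at least 2-fold higher and 96 at least 2-fold lower; with per-array median scaling 58.6% were higher. Against the other 6 mutants the photosynthesis median was also 0.63 (adjusted p = 6.7e-18), the floral promoters passed with 3 of 4 higher (adjusted p = 0.0068), FD no longer among them, and 5 anther and tapetum genes were lower (adjusted p = 8.3e-04).

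The ap1-15 mutant carries a change in AP1, a MADS-box gene of floral meristem, sepal and petal identity. Floral promoters rose in ap1-15: FD by 1.62 ± 0.12, from 45.6 ± 4.9 to 156.4 ± 16.3, AGL71 by 1.57 ± 0.26, AGL42 by 1.04 ± 0.10 and AGL24 by 0.78 ± 0.13. The allantoinase gene ALN rose by 1.23 ± 0.09 and the acyltransferase gene BAT1 by 1.14 ± 0.07. RXF26 fell by 3.94 ± 0.11, from 323.5 ± 6.9 to 14 ± 5.0, and scpl35 by 1.94 ± 0.07. NGA1, a B3-type gene of style and leaf margins, fell by 0.99 ± 0.14, SPT rose by 0.45 ± 0.07, and UFO fell by 0.65 ± 0.18, from 27.7 ± 1.4 to 14.9 ± 4.1 (adjusted p = 0.0068); without ap1-15 replicate B UFO was at -0.52 and did not pass (adjusted p = 0.051, within 0.0014 to 0.051 over the alternatives).

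All 4 floral promoters rose in ap1-15, also when adjusted over the list alone (median 1.304, adjusted p = 5.3e-06, and adjusted p = 0.0021 with an estimated correlation). Photosynthesis genes fell in ap1-15, 8 of 10 with 0 higher and the same counts adjusted over the list alone (median -0.31, adjusted p = 2.6e-05, and adjusted p = 0.017 with an estimated correlation). PSAE-1, a photosystem I subunit, fell by 0.70 ± 0.08 and RCA, which activates Rubisco, by 0.57 ± 0.06. Of 7 Calvin cycle genes 6 fell (median -0.41, adjusted p = 1.2e-04, and adjusted p = 0.012 with an estimated correlation) and of 11 thylakoid genes 6 fell (median -0.29, adjusted p = 0.0021, and adjusted p = 0.22 with an estimated correlation). Among 69 plastid-encoded genes 20 fell and 6 rose (median -0.18, adjusted p = 0.0045, and adjusted p = 0.71 with an estimated correlation). Against the other 6 mutants all 10 photosynthesis (median -0.65), all 7 Calvin cycle (median -0.67) and all 11 thylakoid genes (median -0.54) were lower. None of the other fixed lists passed (adjusted p = 0.38 to 0.76). In all, 4020 probe sets changed, 2051 higher (51.0%) and 1969 lower, with 98 at least 2-fold higher and 192 at least 2-fold lower. With the RNA 3'/5' signal ratio of each array as a covariate (group means 1.56 in ap1-15 and 1.83 in Col-0) 2664 probe sets changed, 2464 of them shared, and with per-array median scaling 62.8% were higher.

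A run of neighbouring genes on chromosome 3 (order from the TAIR10.1 annotation), chosen after their values were seen, was higher in ap1-15. It held 57 measured genes from AT3G03320 to AT3G05060, of which 51 were called higher than in Col-0 and 0 lower. AT3G04840 was at 3804.6 in ap1-15 and 2182.7 in Col-0, a log2 change of 0.80, and BGLU25 was higher by 0.73. The run's median was 0.84 against Col-0 and 0.84 against the other 6 mutants in ap1-15, while its medians in the other 6 mutants against Col-0 lay between -0.07 and 0.01.

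**Figure D3:**
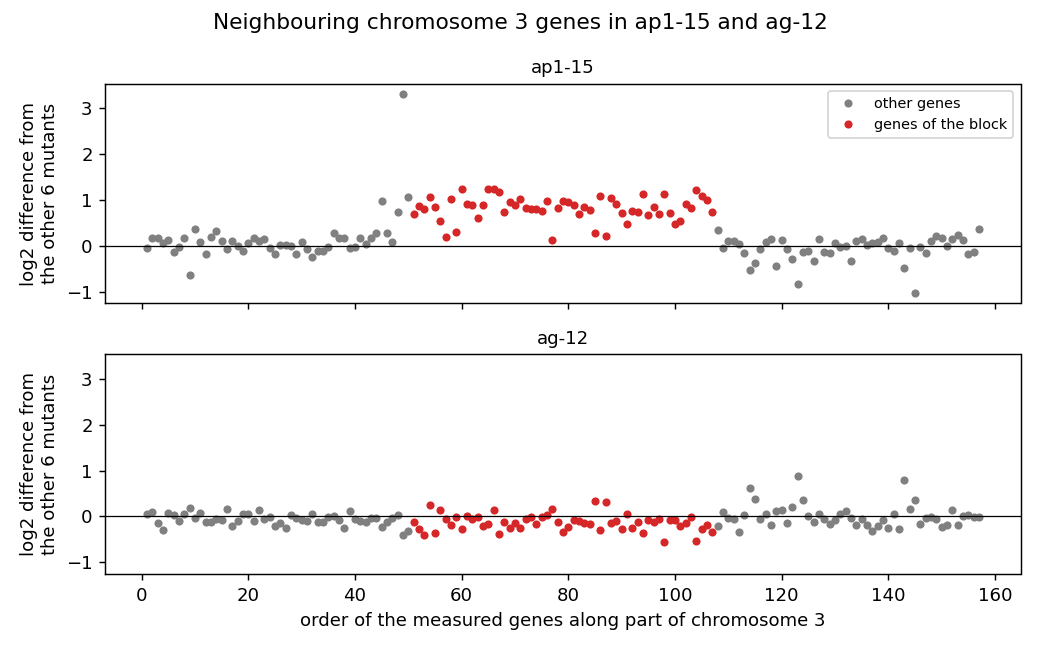
Log2 difference from the mean of the other 6 mutants for measured genes in their order on chromosome 3 (TAIR10.1), in ap1-15 and ag-12, with the genes from AT3G03320 to AT3G05060 in red. In ap1-15 these genes had a median of 0.84.

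The ap2-6 mutant carries a change in AP2, a regulator of sepal and petal identity that also restrains the stamen and carpel gene AG. Genes of the tapetum, the layer that feeds developing pollen, rose in ap2-6: AT5G62080 by 3.72 ± 0.19, AT5G07230 by 3.25 ± 0.18, from 1.3 ± 0.7 to 81.0 ± 3.5, and AT3G52130 by 3.09 ± 0.21. AMS, a tapetal bHLH gene, rose by 1.13 ± 0.27, SWEET8 by 1.45 ± 0.13, the glucosinolate side-chain gene AOP3 by 1.74 ± 0.25 and the jasmonate methyltransferase gene JMT by 1.05 ± 0.20. UFO fell by 1.62 ± 0.18, from 27.7 ± 1.4 to 4.0 ± 3.9 (adjusted p = 1.1e-07), and RXF26 fell by 3.81 ± 0.11.

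All 4 genes of the tapetum and pollen wall list rose in ap2-6 (median 3.17, adjusted p = 5.6e-10, and adjusted p = 8.6e-04 with an estimated correlation), and they also rose against the other 6 mutants (median 3.07, adjusted p = 3.0e-12). Of the 6 genes of the fixed anther and tapetum list 3 rose and 1 fell, with the same counts adjusted over the list alone (median 0.31, adjusted p = 0.045, and adjusted p = 0.14 with an estimated correlation). That list did not pass with per-array median scaling (adjusted p = 0.064), within 4.0e-07 to 0.14 over its alternatives, the lowest being against the other 6 mutants with 5 higher. Of 9 beta-glucosidase genes 4 fell, BGLU45 by 1.32 ± 0.16 and BGLU15 by 0.60 ± 0.14 (median -0.17, adjusted p = 0.012, and adjusted p = 0.17 with an estimated correlation). The photosynthesis list did not pass (adjusted p = 0.93, median 0.07, mean -0.02) and was lower against the other 6 mutants, with 6 of 10 genes down (median -0.19, adjusted p = 5.0e-06, within 5.0e-06 to 0.94). No other fixed list passed (adjusted p = 0.082 to 0.95), and the cell cycle list had a median of 0.01 and a mean of -0.02, and the organ primordium list a median of 0.01 with the test pointing downward. In all, 3030 probe sets changed, 1488 higher and 1542 lower, with 90 at least 2-fold higher and 117 at least 2-fold lower; with per-array median scaling 58.9% were higher.

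The ap3-6 mutant carries a change in AP3, a MADS-box gene of petal and stamen identity. Genes of sporogenous tissue and anthers fell in ap3-6: SPL by 1.71 ± 0.20, from 23.1 ± 2.2 to 1.5 ± 0.2, and EMS1 by 0.78 ± 0.08. REM22 fell by 1.86 ± 0.11, the methionine sulfoxide reductase gene MSRB5 by 1.88 ± 0.14 and LUL1, of the ubiquitin ligases, by 1.80 ± 0.11. AOP3 rose by 2.48 ± 0.25, from 4.8 ± 4.1 to 61.1 ± 5.7, and SWEET10 by 1.55 ± 0.07. UFO was higher by 0.59 ± 0.18 (adjusted p = 0.015), but did not pass without Col-0 replicate B (0.57, adjusted p = 0.052), without ap3-6 replicate B (0.49, adjusted p = 0.085) or without ap3-6 replicate C (0.56, adjusted p = 0.056), within 1.0e-06 to 0.085 over the alternatives.

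Of 6 anther and tapetum genes 4 fell, 5 when adjusted over the list alone (median -0.73, adjusted p = 0.0023, and adjusted p = 0.022 with an estimated correlation), and 5 were lower against the other 6 mutants (adjusted p = 0.0011). Of 10 photosynthesis genes 6 rose and 0 fell, with the same counts adjusted over the list alone (median 0.23, adjusted p = 0.028, and adjusted p = 0.22 with an estimated correlation), and of 11 thylakoid genes 6 rose (median 0.21, adjusted p = 0.019, and adjusted p = 0.34 with an estimated correlation). The photosynthesis list did not pass after quantile normalization (median 0.12, adjusted p = 0.33) and turned to a median of -0.03 against the other 6 mutants (adjusted p = 0.62), within 0.014 to 0.62 over the alternatives. The thylakoid list turned too, to a median of -0.01 with 2 higher and 4 lower (adjusted p = 0.45, within 0.0060 to 0.45). Of 7 autophagy genes 3 fell, ATG8F by 0.47 ± 0.07 (adjusted p = 0.047, and adjusted p = 0.41 with an estimated correlation); against the other 6 mutants 2 were lower and the list did not pass (adjusted p = 0.17, within 0.045 to 0.41). The other fixed lists did not pass (adjusted p = 0.22 to 0.83), and the cell cycle list had a median of 0.09 and a mean of -0.09. In all, 3483 probe sets changed, 1660 higher (47.7%) and 1823 lower, with 55 at least 2-fold higher and 148 at least 2-fold lower. With per-array median scaling 71.8% were higher.

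The ag-12 mutant carries a change in AG, a MADS-box gene of stamen and carpel identity. SPL fell by 1.77 ± 0.20, from 23.1 ± 2.2 to 1.1 ± 0.3, EMS1 by 0.61 ± 0.08 and the glutaredoxin gene ROXY2, which acts in anthers, by 1.5 ± 0.23. REM22 fell by 2.90 ± 0.11, from 254.1 ± 21.5 to 27.0 ± 2.4, and chr31 by 2.24 ± 0.12, with its further probe set at -0.64. COR15A rose by 2.97 ± 0.16, SWEET10 by 1.62 ± 0.07, the cellulose synthase-like gene CSLA01 by 1.38 ± 0.14 and CYP71B26 by 1.29 ± 0.10. UFO was at 20.6 ± 2.8 against 27.7 ± 1.4 and did not pass (adjusted p = 0.19).

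All 10 photosynthesis genes rose in ag-12, also when adjusted over the list alone, with LHCB4.2 at 0.84 ± 0.06 and LHCB4.3 at 0.76 ± 0.10 (median 0.60, adjusted p = 8.3e-14, and adjusted p = 3.9e-04 with an estimated correlation). All 7 Calvin cycle genes rose (median 0.36, adjusted p = 1.7e-07, and adjusted p = 0.0018 with an estimated correlation), as did all 11 thylakoid genes (median 0.51, adjusted p = 1.2e-13, and adjusted p = 0.0032 with an estimated correlation). Of 69 plastid-encoded genes 23 rose and 9 fell (median 0.18, adjusted p = 7.8e-04, and adjusted p = 0.68 with an estimated correlation), which did not pass after quantile normalization (adjusted p = 0.080, within 4.6e-09 to 0.68). Of 6 anther and tapetum genes 4 fell, with the same count adjusted over the list alone (median -0.66, adjusted p = 0.0030, and adjusted p = 0.025 with an estimated correlation). The floral promoters did not pass against Col-0 (adjusted p = 0.77) and all 4 were lower against the other 6 mutants (median -0.77, adjusted p = 3.8e-04, within 3.8e-04 to 0.82). None of the other fixed lists passed (adjusted p = 0.36 to 0.58), and the organ primordium list had a median of 0.01 and a mean of -0.22. In all, 3930 probe sets changed, 1821 higher (46.3%) and 2109 lower, with 54 at least 2-fold higher and 89 at least 2-fold lower. With per-array median scaling 59.1% were higher.

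The ufo-1 mutant carries a change in UFO, whose F-box protein acts with LFY to turn on AP3. UFO itself was at 18.3 ± 2.7 in ufo-1 against 27.7 ± 1.4 in Col-0, a log2 change of -0.44 ± 0.18 that did not pass (adjusted p = 0.084); it passed with all 42 arrays in a single fit (adjusted p = 0.041, within 0.041 to 0.46 over the alternatives). SWEET10 rose by 1.47 ± 0.07, ECS1 by 1.255 ± 0.07 and AT5G07230 by 1.21 ± 0.18, and ROXY2 fell by 1.29 ± 0.23. Of 10 photosynthesis genes 7 rose, 8 when adjusted over the list alone, with LHCB4.2 at 0.65 ± 0.06 (median 0.36, adjusted p = 2.8e-09, and adjusted p = 0.0018 with an estimated correlation). Of 7 Calvin cycle genes 4 rose (median 0.28, adjusted p = 9.3e-05, and adjusted p = 0.012 with an estimated correlation) and of 11 thylakoid genes 9 rose (median 0.35, adjusted p = 7.3e-11, and adjusted p = 0.0088 with an estimated correlation). Against the other 6 mutants the medians were smaller, 0.13 for photosynthesis with 4 of 10 higher, 0.09 for the Calvin cycle with 2 of 7 and 0.14 for the thylakoid list with 5 of 11.

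Of 7 autophagy genes 4 fell in ufo-1, ATG8D by 0.69 ± 0.11 (median -0.34, adjusted p = 0.0058, and adjusted p = 0.23 with an estimated correlation), and of 6 histone genes 4 fell (median -0.33, adjusted p = 0.024, and adjusted p = 0.29 with an estimated correlation). Of 9 cytochrome P450 genes 2 rose, CYP71B22 by 0.67 ± 0.08 (median 0.07, adjusted p = 0.045, and adjusted p = 0.13 with an estimated correlation), and of 69 plastid-encoded genes 18 rose and 8 fell (median 0.13, adjusted p = 0.0027, and adjusted p = 0.71 with an estimated correlation). The anther and tapetum list did not pass, with 4 of 6 genes lower and 1 higher (median -0.56, adjusted p = 0.082); it passed with per-array median scaling (adjusted p = 0.021, within 0.021 to 0.45 over the alternatives). The plastid-encoded list did not pass after quantile normalization (adjusted p = 0.68, within 1.3e-06 to 0.71), and against the other 6 mutants neither the histone list (adjusted p = 0.31, within 3.5e-04 to 0.31) nor the cytochrome P450 list, with 1 of 9 higher (adjusted p = 0.13, within 0.021 to 0.13), passed. No other fixed list passed (adjusted p = 0.26 to 0.59). In all, 2748 probe sets changed, 1375 higher (50.04%) and 1373 lower, with 65 at least 2-fold higher and 71 at least 2-fold lower. With the RNA 3'/5' ratio as a covariate (2.03 in ufo-1 and 1.83 in Col-0) 1771 changed, 1622 of them shared, and with per-array median scaling 77.6% were higher.

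**Figure D4:**
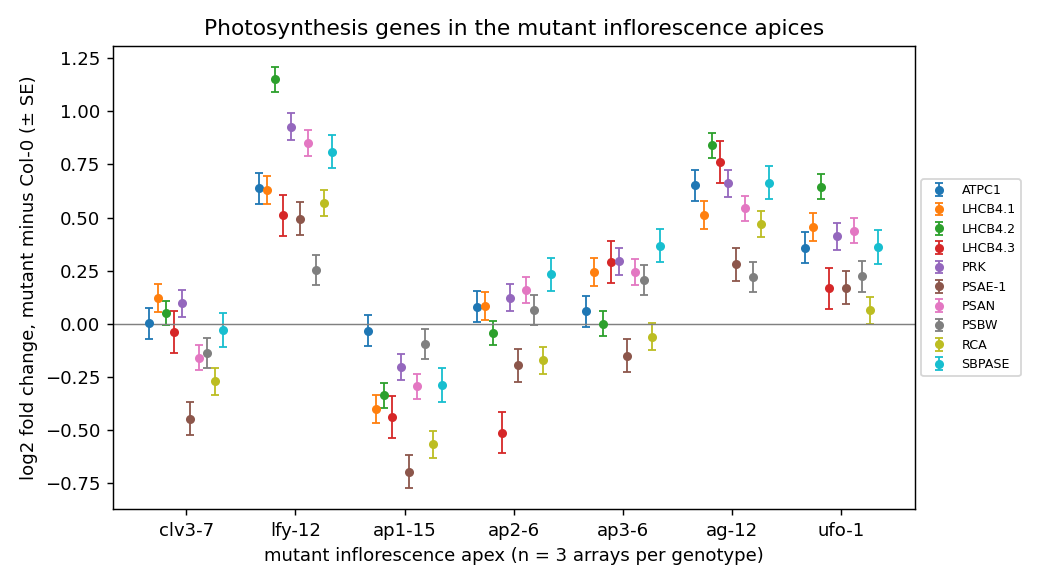
Log2 fold change against the Col-0 inflorescence apex ± standard error of 10 photosynthesis genes in the 7 mutants. All 10 were higher in lfy-12 and ag-12, and 8 of 10 were lower in ap1-15.

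The ufo-1 and ap3-6 apices were compared directly, since both genes act in petal and stamen identity. MSRB5 was higher in ufo-1 by 2.40 ± 0.14, THI2.1 by 1.94 ± 0.06, at 1442.2 ± 75.6 against 371.0 ± 32.2, LUL1 by 1.66 ± 0.11 and CSA1 by 1.41 ± 0.14. UFO was lower in ufo-1 than in ap3-6 by a log2 change of -1.04 ± 0.18, AOP3 by -2.51 ± 0.25, and LigB and MT1C by -1.20 ± 0.13 and -1.21 ± 0.17. Of 10 photosynthesis genes 5 were higher and 0 lower in ufo-1, with the same counts adjusted over the list alone and LHCB4.2 at 0.65 ± 0.06 (median 0.16, adjusted p = 0.0058, and adjusted p = 0.13 with an estimated correlation). Of 11 thylakoid genes 6 were higher (median 0.19, adjusted p = 0.0023, and adjusted p = 0.22 with an estimated correlation), and of 9 beta-glucosidase genes 3 were higher, BGLU28 by 1.3 ± 0.17 (median 0.13, adjusted p = 0.029, and adjusted p = 0.22 with an estimated correlation). The other fixed lists did not pass (adjusted p = 0.091 to 0.94), and the floral promoters had a median of 0.04 and a mean of -0.04, and the cell cycle list a median of -0.11 with the test pointing upward. In all, 2690 probe sets differed, 1411 higher and 1279 lower, with 139 at least 2-fold higher and 71 at least 2-fold lower.

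The lfy-12 and ap1-15 apices were compared directly, since both genes specify floral meristems. RXF26 was higher in lfy-12 by 4.29 ± 0.11, UF3GT by 2.1 ± 0.13, GLC by 2.00 ± 0.14, STOMAGEN, a peptide that promotes stomata, by 1.97 ± 0.12 and scpl35 by 1.72 ± 0.07. REM22 was lower in lfy-12 by a log2 change of -2.70 ± 0.11, SPL by -1.72 ± 0.20 and the cold- and clock-regulated gene COR27 by -1.57 ± 0.10. All 10 photosynthesis genes were higher in lfy-12, also when adjusted over the list alone, with LHCB4.2 at 1.49 ± 0.06 (median 1.11, adjusted p = 1.0e-17, and adjusted p = 2.4e-04 with an estimated correlation). All 7 Calvin cycle genes (median 1.10, adjusted p = 2.2e-12, and adjusted p = 2.5e-04 with an estimated correlation) and all 11 thylakoid genes (median 0.79, adjusted p = 3.9e-17, and adjusted p = 0.0015 with an estimated correlation) were higher. Of 6 anther and tapetum genes 4 were lower, with the same count adjusted over the list alone (median -0.69, adjusted p = 0.0033, and adjusted p = 0.025 with an estimated correlation).

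Among 69 plastid-encoded genes 30 were higher in lfy-12 than in ap1-15 and 0 lower (median 0.29, adjusted p = 1.8e-09, and adjusted p = 0.42 with an estimated correlation). Of 5 GSTU glutathione transferase genes 4 were higher, GSTU18 by 0.69 (median 0.50, adjusted p = 0.0029, and adjusted p = 0.025 with an estimated correlation). Of 9 cytochrome P450 genes 4 were higher, CYP71B26 by 1.65 (median 0.33, adjusted p = 0.024, and adjusted p = 0.088 with an estimated correlation), and of 13 serine carboxypeptidase-like genes 6 were higher and 3 lower (median 0.32, adjusted p = 0.028, and adjusted p = 0.17 with an estimated correlation). None of the other fixed lists passed (adjusted p = 0.28 to 0.88), and the organ primordium list had a median of -0.03 and a mean of 0.03. In all, 4609 probe sets differed, 2207 higher and 2402 lower, with 309 at least 2-fold higher and 140 at least 2-fold lower. With the RNA 3'/5' ratio as a covariate (1.82 in lfy-12 and 1.56 in ap1-15) 3300 differed, 1779 of them higher and 3090 shared.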

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

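The tests of a chromosome 3 run in ap1-15, of stem tissue behind the photosynthesis genes, of changes shuffled between probe sets and of the size of change left by quantile normalization were chosen only after the result was seen, as was the use of the other 6 mutants as a reference for lists and genes.

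Between lfy-12 and ap1-15, the lists and named genes below changed in opposite directions against the same Col-0 arrays. They were kept because they passed in both mutants and in the direct comparison, for lists with the preset correlation. That each passed is therefore the rule of choice, not a further result, and several of the genes belong to these lists. The photosynthesis list differed by 1.11 (median log2; 0.63 in lfy-12 and -0.31 in ap1-15), the Calvin cycle list by 1.10 (0.57 and -0.41), the thylakoid list by 0.79 (0.54 and -0.29) and the plastid-encoded genes by 0.29 (0.13 and -0.18). With an estimated correlation the plastid-encoded genes did not pass directly (adjusted p = 0.42) nor in lfy-12 (adjusted p = 0.75) or ap1-15 (adjusted p = 0.71), and the thylakoid list did not pass in ap1-15 (adjusted p = 0.22). RXF26 differed by 4.29 (0.35 and -3.94), GLC by 2.00 (0.74 and -1.26), STOMAGEN by 1.97 (0.71 and -1.26) and CYP71B26 by 1.65 (1.24 and -0.41). LHCB4.2 differed by 1.49, PSAE-1 by 1.19, HPR by 1.16, PSAN by 1.14, RCA by 1.14, PRK by 1.13, SBPASE by 1.10 and LHCB4.1 by 1.03, each higher in lfy-12 and lower in ap1-15 than in Col-0. The serine carboxypeptidase gene scpl20 differed by 0.89 and YAB3 by 0.70 in the same sense, and COR27 by -1.57 in the opposite one (-1.24 in lfy-12 and 0.34 in ap1-15).

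The same rule was used between ufo-1 and ap3-6. MSRB5 differed by 2.40 (0.52 in ufo-1 and -1.88 in ap3-6), THI2.1 by 1.94 (0.69 and -1.251) and BGLU28 by 1.302 (0.52 and -0.79). LigB differed by -1.20 (-0.39 in ufo-1 and 0.81 in ap3-6). The added poly-A controls, outside the plant measurement, were raised on the node arrays, with means of 8.07 for dap, 5.24 for lys, 7.15 for thr and 5.77 for phe. On the Col-0 inflorescence apex arrays they were at 7.71, 4.90, 6.70 and 5.30, while the other 36 arrays averaged 3.20, 3.47, 3.52 and 3.32.

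The 135 probe sets called in the same direction in all 7 mutants, among them lower ndhF, QQS and petD, were weighed first. With each mutant's changes shuffled over probe sets and the same 3 reference arrays kept for all 7, at most 8 were shared in 100 draws. A preparation of the Col-0 arrays shared with the node arrays would put the node on the Col-0 side. The node lay on the other side of the other Col-0 organs (median -0.25, quartiles -0.66 to 0.01). The node is also a different organ, and 98.4% of probe sets differed among the organs, so its position cannot decide. QQS, petN, ndhE, petG and ycf3 were on the Col-0 side in the node (by 1.87, 0.37, 0.61, 0.44 and 0.45). A shared preparation stays open. After quantile normalization 88.1% were still called in all 7 mutants, short of the 90% set in advance for arguing against a change of the whole scale. By the size of change, a criterion set afterwards, the median was 0.993 of that before (quartiles 0.964 to 1.02), with 77 higher and 58 lower as before, which argues against it as the whole cause. A preparation that differed for the Col-0 inflorescence apex alone may account for part of these differences; it cannot be told apart from the genotype, because all 3 Col-0 arrays share it. An effect common to the 7 mutations stays open too and was not tested.

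The run of 57 neighbouring chromosome 3 genes higher in ap1-15 was weighed next, together with genes near each mutated gene. A chance run has little support, since the densest window of ap1-15 held 17 genes at least 2-fold apart and 1000 random gene orders gave at most 10. A segment of another strain would hold lower as well as higher genes, but 100% of 28 held-out genes of the run were higher in ap1-15 than in the other 6 mutants (median 0.89, quartiles 0.80 to 1.04), which argues against it. For an extra copy of the segment, 100% of these genes exceeded the smallest fold set for it, and 5 of all 57 did not, each among the genes by which the run was found; this is consistent with that candidate explanation, while coordinated local regulation was not tested. Around the mutated genes of clv3-7, ap1-15, ap2-6, ap3-6, ag-12 and ufo-1 the window held 0 such genes; 100% of windows hold at least 0, so this test cannot decide there. In lfy-12 it held 3 (AT5G60250, AT5G61120 and AT5G62080, chosen after their values were seen), and 5.85% of windows held as many. A segment of another strain around the mutated gene stays open in all 7 mutants.

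The rise of photosynthesis genes in lfy-12, ag-12, ufo-1 and ap3-6 was weighed last. In ap3-6 it did not hold after quantile normalization or against the other 6 mutants. If it came from more stem tissue in the sample, internode shares of 22.7%, 15.1%, 10.4% and 6.20% would be needed. Those shares would also bring the 9 xylan genes, but the median measured rise of these genes was 0.00286, 0.00853, -0.00592 and 0.0104 of the level required, in that order. The highest single genes reached 0.0420, 0.183, 0.0533 and 0.265 of it. This argues against tissue like the second internode as the cause. Stem tissue with lower levels of the xylan genes was not tested. More leaf-like organs in these apices may account for the rise and were not tested, and the genotype itself stays open.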

How the results depend on the processing

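The alternatives with the mean of other mutants in place of Col-0, for lists, genes and organ contrasts, and the organ fits without the node and Col-0 inflorescence apex arrays were chosen only after the result was seen.

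Counts of changed probe sets stayed within 1.5 times in 298 of 317 alternatives, counts of at least 2-fold changes in 271 of 317 and the F tests in 20 of 22. Lists kept their direction and their side of the threshold in 1275 of 1388 alternatives, with 93 weaker, 14 stronger and 6 reversed, and named genes in 7266 of 7435, with 142 weaker, 2 stronger and 25 reversed. Leaving out any single array moved no count of changed probe sets by more than 1.5 times. A replicate block gave 8555 probe sets for transition against vegetative apex, and 15782 and 10114 in the F tests. Signals near the background limit small changes, since the offset compresses them. Without the node and Col-0 inflorescence apex arrays the counts were 8289 (8189 shared) for transition against vegetative apex, 7444 (7331 shared) with young leaves and 11937 (11866 shared) for hypocotyl against internode.

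With only probe sets of 1 gene, fewer were tested, and the counts in the order of the organ comparisons were 4423, 2533, 4983, 3990, 4824, 6450 and 7288, with 1352 in clv3-7, 1861 in lfy-12, 1900 in ap1-15, 1438 in ap2-6, 1706 in ap3-6, 1883 in ag-12, 1222 in ufo-1, 1308 for ufo-1 against ap3-6 and 2153 for lfy-12 against ap1-15. All of them were among the calls of the full fits, and the F tests gave 8568 and 5293. The counts at least 2-fold apart were 500, 162, 701, 217, 605, 1985 and 3534 in the organs, 45 in clv3-7, 82 in lfy-12, 125 in ap1-15, 103 in ap2-6, 99 in ap3-6, 57 in ag-12, 53 in ufo-1, and 104 and 206 in the direct comparisons. With 4 times the offset, which shrinks changes at low signal, they were 549, 165, 829, 206, 698 and 2593 in the first 6 organ comparisons, 31 in clv3-7, 86 in lfy-12, 119 in ap1-15, 88 in ap2-6, 89 in ap3-6, 53 in ag-12, 40 in ufo-1, and 80 and 206 in the direct comparisons. With the offset divided by 4, which widens them, they were 582 for inflorescence against transition apex, 753 with young leaves, 170 in clv3-7, 219 in ag-12 and 318 for ufo-1 against ap3-6. The filter at the 60th percentile tested fewer probe sets and gave 52 in clv3-7, 136 in lfy-12, 116 in ap2-6, 92 in ag-12, 70 in ufo-1 and 133 for ufo-1 against ap3-6.

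With the RNA 3'/5' ratio as a covariate 2664 probe sets changed in ap1-15 and 1771 in ufo-1; the cause was not tested. Against the mean of the other 6 mutants 4779 changed in clv3-7, and those at least 2-fold apart were 113 in lfy-12, 124 in ap2-6, 123 in ap3-6 and 64 in ufo-1; the cause was not tested. The correlation of fold changes reversed against the other 5 mutants for clv3-7 and lfy-12 (-0.0444), lfy-12 and ap1-15 (-0.0809), lfy-12 and ap2-6 (-0.130), ap1-15 and ap3-6 (-0.0476), ap1-15 and ag-12 (-0.247), ap1-15 and ufo-1 (-0.0918), and ap2-6 and ag-12 (-0.206); the cause was not tested.

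Among the lists, against the mean of mutants the thylakoid genes reversed for inflorescence against transition apex (0.0913). In ap2-6 the photosynthesis (-0.19) and thylakoid genes (-0.13) did so, and in ap3-6 the photosynthesis (-0.0268) and thylakoid genes (-0.0111). The Calvin cycle genes in ap2-6 reversed only in the direction of the test, with a median of -0.03 against Col-0 and -0.20 against the other mutants. The cause was not tested. Against the other 6 mutants further lists passed that had not against Col-0. Among them were carpel and ovule in ap2-6 (median 0.23), and the tapetum and pollen wall list in lfy-12 (-0.80), ap3-6 (-0.66) and ag-12 (-0.66). For lfy-12, ap3-6 and ag-12 the reference includes ap2-6, where the tapetum and pollen wall list rose, which lowers these values. Other causes were not tested. Genes reversed with the same reference: for inflorescence against transition apex UFO (-0.13) and PSAN (0.00988), in clv3-7 COR15A (-0.23), in lfy-12 UFO (0.36), rps14 (0.58), petN (0.41) and ndhF (0.45), in ap2-6 BGLU42 (0.00972), in ap3-6 PRK (-0.0425), PSAN (-0.0111) and ndhF (0.23), in ag-12 HTB1 (0.0149), petN (0.15) and ndhF (0.39), and in ufo-1 QQS (0.26); the cause was not tested. RCA reversed for internode against node with quantile normalization (-0.0328), and UFO in lfy-12, near 0, with quantile normalization (0.0338), per-array median scaling (0.0259) and 4 times the offset (0.000302); the cause was not tested. Leaving out 1 array gave UFO values of -0.0865 to 0.0550 in lfy-12 and -0.0954 to 0.0200 with young leaves.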

Other observations

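The count of shared probe sets between mutants was fixed in advance; the choice of example genes was not.

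Pairs of mutants shared more changed genes than independent lists would. The largest overlap of the 21 pairs was between lfy-12 and ag-12, with 2277 probe sets changed in the same direction (1148 higher, 1129 lower) against 531 for independent lists; REM22, SPL and chr31 were lower and COR15A, LHCB4.2 and PRK higher in both. Over all pairs the shared counts ran from 654 to 2277 and the independent ones from 262 to 543. With each mutant's changes shuffled over probe sets but the reference arrays shared, a test chosen after the result was seen, pairs had 368 to 1309 such probe sets over 100 draws, with 2943 to 5579 calls per mutant against 2748 to 4020 measured. The shared reference together with unrelated changes of each mutant can thus give counts like the lower ones. Those of 7 pairs, 1351 to 2277, lay above these draws. The draws held no deviation common to the 3 Col-0 arrays, such as a separate preparation of them could bring. Such a deviation could also raise the counts, so they do not separate it from a shared response. Without any changes, simulated groups compared with the same 3 arrays shared at most 1 such probe set in 100 draws. Fold changes correlated across probe sets, which are not independent replicates, at 0.684 for lfy-12 and ag-12 and at 0.593 for ap1-15 and ap2-6, where RXF26 fell in both, and at 0.124 for ap1-15 and ag-12. Unchanged simulated groups compared with the same 3 arrays gave a mean correlation of 0.476 (-0.608 to 0.815 over 100 draws), so the correlations alone do not separate a shared response from the shared reference. The covariances ran from 0.0132 to 0.0672, all but that of ap1-15 and ag-12 (0.0132) above the simulated range of -0.0028 to 0.0154. The simulated groups held no common deviation of the Col-0 arrays either. Against the mean of the other 5 mutants the correlation was 0.599 for lfy-12 and ag-12, and -0.247 for ap1-15 and ag-12.

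The signal of UFO was 1.73 ± 0.84 in the vegetative apex and 1.57 ± 0.40 with young leaves, 23.5 ± 2.2 in the transition apex and 27.7 ± 1.4 in the Col-0 inflorescence apex (SD, n = 3). It was 0.559 ± 0.068 in the node, 1.59 ± 0.39 in the internode and 1.37 ± 0.31 in the hypocotyl. Among the mutants it ran from 4.0 ± 3.9 in ap2-6 to 46.4 ± 9.3 in ap3-6, with 34.6 ± 3.3 in clv3-7.

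For each comparison of 3 arrays with 3 there are 10 splits, which cannot give a share under 0.05. The real split gave 8602 probe sets for transition against vegetative apex and the highest other split 1, and 5155 and 2 for inflorescence against transition apex, 9727 and 2 for inflorescence against vegetative apex, and 7737 and 1 with young leaves. It gave 9180 and 2 for internode against node, 12172 and 0 for hypocotyl against internode, and 13597 and 0 for internode against inflorescence apex. The mutants gave 2793 and 1 in clv3-7, 3952 and 1 in lfy-12, 4020 and 1 in ap1-15, 3030 and 0 in ap2-6, 3483 and 0 in ap3-6, 3930 and 0 in ag-12, and 2748 and 0 in ufo-1. The direct comparisons gave 2690 and 1 for ufo-1 against ap3-6 and 4609 and 1 for lfy-12 against ap1-15. For the F tests 1 of 100 labellings, the real one, gave as many probe sets: 15790 against at most 7897 in the organs and 10253 against at most 299 in the genotypes. That is the smallest share that 100 labellings can give. It argues against a random grouping of these arrays, but shows no difference beyond these samples, which may be technical repeats.

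Next to the run on chromosome 3, AT3G03290, chosen after its values were seen, was higher in ap1-15 by 3.31 than in the other 6 mutants. Running medians of 21 neighbouring genes over the whole genome reached 0.90 in ap1-15 and at most 0.24 in the other mutants, with a lowest value of -0.32 in ap3-6. The mean log2 3'/5' ratio of the RNA controls ran from 1.35 in the vegetative apex to 2.03 in ufo-1, with 1.41 in the node, 1.56 in ap1-15 and 1.83 in the Col-0 inflorescence apex.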
